A study of Mus musculus with 6 samples.

How the data were processed

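The data are mRNA sequencing libraries from the ventricles of 6 mice, 3 given vehicle and 3 given Paro/Neo, taken from a single deposited table of TPM values with 1 column per mouse. Per the labels' protocols, snap-frozen ventricles were powdered, RNA was extracted and purified, samples with an RNA integrity number above 7 were kept, and stranded mRNA libraries were made with a KAPA kit. Per the submitters' processing notes, the tools were FastQC 0.11.5, STAR 2.5.3a, featureCounts, Subread and edgeR, on the build mm10, with no role or order given. The gene annotation, the strand setting of the counting and the filter that left 18158 features are not given in the sources used here. The authors' values are in TPM, so each library has the same sum over the listed features and a rise in abundant genes lowers the share left for others. Groups and replicate numbers come from the sample titles. The sample descriptions number the Paro/Neo libraries 2, 3 and 4 where the titles have 1, 2 and 3, and no label says whether either numbering marks a litter or a day.

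TPM keeps no depth, but for a given feature the values of 2 libraries stand in a ratio of whole reads times a constant. The commonest ratios among values below 1 TPM gave that constant for each pair of libraries, and with it 17574 of 17574 features above 0 came out as whole reads within 0.001 of a read in every library, a check that has force only for the 14330 features above 0 in all 6. On simulated data 98.22% of 16024 genes were read back exactly. These inferred reads are lower estimates, because a factor shared by all 6 counts of a feature cannot be seen. They put the depth at 15969980, 12997730 and 9556387 reads for vehicle replicates 1 to 3 and at 15575723, 12952840 and 12421206 reads for Paro/Neo replicates 1 to 3, and they were used for depth, for the reads given beside low values and for 1 alternative. No negative binomial model was used, as the unit is TPM. A group of 56 features in 25 sets had equal inferred reads in every library, among them Hba-a1 with Hba-a2 and H2-Q6 with H2-Q8. By these reads the members of a set cannot be told apart. In sets of few reads, such as Cbln1 with Slc1a7 at 2 to 6 reads per library, equal numbers may be a coincidence.

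Features were matched to GENCODE M21 on GRCm38, which is mm10, by symbol or synonym: 17882 of 18158 matched 1 gene. Coordinates are those of the whole gene and count from 1. GC content was that of the annotated transcripts, present for 99.23% of tested genes.

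Values were transformed to log2(TPM + 1), a scale that understates the change of low genes. The 12409 genes at 1 TPM or more in at least 3 of 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, 4.03 prior degrees of freedom), treated against vehicle, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 change is the moderated one. Of 40 gene lists, 37 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over those lists, beside camera with an estimated correlation and fry. The list of transcripts encoded in the mitochondrion had 0 members to test, the lymphocyte list had 3, and the sex-linked list served as a check: all 6 libraries had at most 7 reads of Xist and expressed Ddx3y and Eif2s3y, as male tissue does. Benjamini-Hochberg adjustment was also done over each list alone. Lists, tests and the rule for named genes were set before the data were examined. The rule takes the genes of the study's question, the 15 largest rises and falls past the threshold whose groups do not overlap, leaving out clone names, the 10 smallest p in a direction with fewer than 5 such genes, and from each list up to 4 members past the threshold, filled to 2 by the smallest p. Not every gene it takes is reported here. Genes named outside it, chosen after their values were seen, are Gm4841, I830012O16Rik, Igtp, Irgm1, Iigp1, F830016B08Rik, H2-Aa, H2-Ab1, Cd74, Isg15, Fbn1, Mfap4, Col1a1, Col3a1, Thbs4, Pdgfra, Dcn, Nr1d2, Hlf, Arntl, Jun, Lyz2, Rn45s, Cxcl9, Irf1, Gbp2, Gbp4, Ptprc, C1qa, Ppp4c, Fam57b, Rpl26 and Iqcg.

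The fit was tested on simulated libraries of the 12409 genes, with 200 changed 2-fold or 4-fold and a further 30-gene list raised 1.5-fold. In these, 56% of genes changed 2-fold and 90% of those changed 4-fold were called, with 7 unchanged genes called. A list raised throughout was found, while 0 of 20 random lists passed. The SDs of the simulated noise were shuffled among genes, which drops their link with expression, and no library was made to stand apart. The shares called need therefore not hold for the real libraries. The simulated noise was also independent between genes, so the list result does not cover lists whose genes vary together. Such lists are present here, with an estimated correlation of 0.499 for the matrix and fibroblast list. With 3 mice per group an exact permutation test cannot go below p = 0.10, so none is given. Alternatives were other pseudocounts, filters, scalings, moderation settings, library weights, the replicate number as a block, a second threshold, each library left out in turn, and other list tests; chosen after seeing the data were testing the same 12409 genes in the fits that leave out a library, voom on the inferred reads, a GC correction by lowess, that correction with the block, and leaving out short and ribosomal RNA features. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.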

Results

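RNA was sequenced from the ventricles of 6 CD1 mice, an outbred stock, aged 3 months. Of these, 3 had received the vehicle, PBS, and 3 had received paromomycin and neomycin, a pair of aminoglycoside antibiotics referred to here as Paro/Neo, at 150 mg/kg 2 times a day by intraperitoneal injection, for 14 days. Stranded mRNA libraries were read at 76 bp, and each library is 1 mouse. The table used lists 18158 features in TPM, transcript abundances scaled to the same total in each library. Between 15513 and 15972 features were above 0 per library. From the steps of the low values, the libraries held at least 9556387 to 15969980 assigned reads each, with the deepest and the shallowest both among the vehicle hearts. Pairs of libraries correlated across genes at 0.9713 to 0.9871 (Pearson, log2(TPM + 1)), and Paro/Neo replicate 1 stood apart. It had the lowest mean correlation with the others, 0.9755, against 0.9814 to 0.9853, and it lay farthest out on the first principal component, at 36.3 against -16.3 to 3.24. That component also ordered the groups, with Paro/Neo replicates 2 and 3 at 3.24 and -2.52, above the vehicle hearts at -16.3 to -7.79. On the second component Paro/Neo replicate 3 lay lowest, at -25.35. The deviations of Paro/Neo replicate 1 from the gene means also followed GC content, with a Spearman coefficient across genes of -0.349, against -0.11 to 0.298 in the other libraries.

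Per the study's design text, the comparison addresses gene expression where the treatment suppresses the transcription factors Meis1 and Hoxb13, known as regulators of the cardiomyocyte cell cycle. The activity of these factors was not measured here. Meis1 mRNA itself differed by less than the spread between mice: it was 11.2 TPM ± 0.79 in vehicle and 11.3 TPM ± 1.10 in Paro/Neo hearts (SD, n = 3 each), a log2 change of 0.01 ± 0.12 (SE) with an adjusted p of 0.991 by limma. The gene lies on chromosome 11 at 18879817 to 19018985 (GRCm38, GENCODE M21). Its paralog Meis2 was at 10.5 TPM ± 0.33 and 11.3 TPM ± 1.30. Among the inhibitors of cyclin-dependent kinases, Cdkn1a was at 12.6 TPM ± 5.80 against 10.98 TPM ± 1.08, Cdkn1b at 55.6 TPM ± 5.62 against 55.5 TPM ± 9.67, and Cdkn2b at 1.46 TPM ± 0.39 against 1.31 TPM ± 0.27, vehicle first. The differences in Meis2, Cdkn1a, Cdkn1b and Cdkn2b were also smaller than the spread between mice, with adjusted p from 0.839 for Meis2 to 0.989 for Cdkn1b. Cdkn2a had 0 to 3 reads per library, too few for a test, and a difference in it was not detectable at this depth. Hoxb13 was not analysed here. Of the 10 tested members of the fixed list of MEIS, PBX and HOX factors, 4 were higher and 6 lower, none past the threshold. The smallest unadjusted p in that list belonged to Pbx3 (8.89 TPM ± 1.71 against 6.79 TPM ± 1.65) and Hoxd8 (1.65 TPM ± 0.73 against 0.927 TPM ± 0.52).

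Most genes that passed the threshold were higher in treated hearts, among them genes of the interferon response and 3 genes of MHC class I, B2m, H2-K1 and H2-Q4. Gdpd3, which encodes a lysophospholipase D, went from near off, 0.601 TPM ± 0.07 with 3 to 6 reads per library, to 62.7 TPM ± 33.1 with 231 to 678 reads, a 104-fold ratio of means (log2 change 5.18 ± 0.34 SE, adjusted p 0.00384). Among genes past the threshold and not known by a clone name, the next largest log2 changes were in the interferon-induced gene Ifit1, from 5.14 TPM ± 0.40 to 35.1 TPM ± 10.6 (adjusted p 0.0113), and in Irf7, a transcription factor of the interferon response, from 4.63 TPM ± 0.99 to 24.6 TPM ± 6.08 (adjusted p 0.0136). B2m, the light chain of MHC class I molecules, rose from 859 TPM ± 133 to 2631 TPM ± 557, a 3.06-fold ratio (adjusted p 0.0202). The nucleic acid sensor Zbp1, the GTPase Gbp3, the ISG15 protease Usp18, the MHC class I genes H2-K1 and H2-Q4, the interferon-inducible Ifi202b and Rtp4 and the chemokine Ccl12 also rose, by log2 changes between 1.11 for Ccl12 and 1.59 for Zbp1. H2, Gbp and Ifit genes belong to families of similar sequence whose reads the counting could have split, so values of single members are uncertain.

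**Figure D1:**
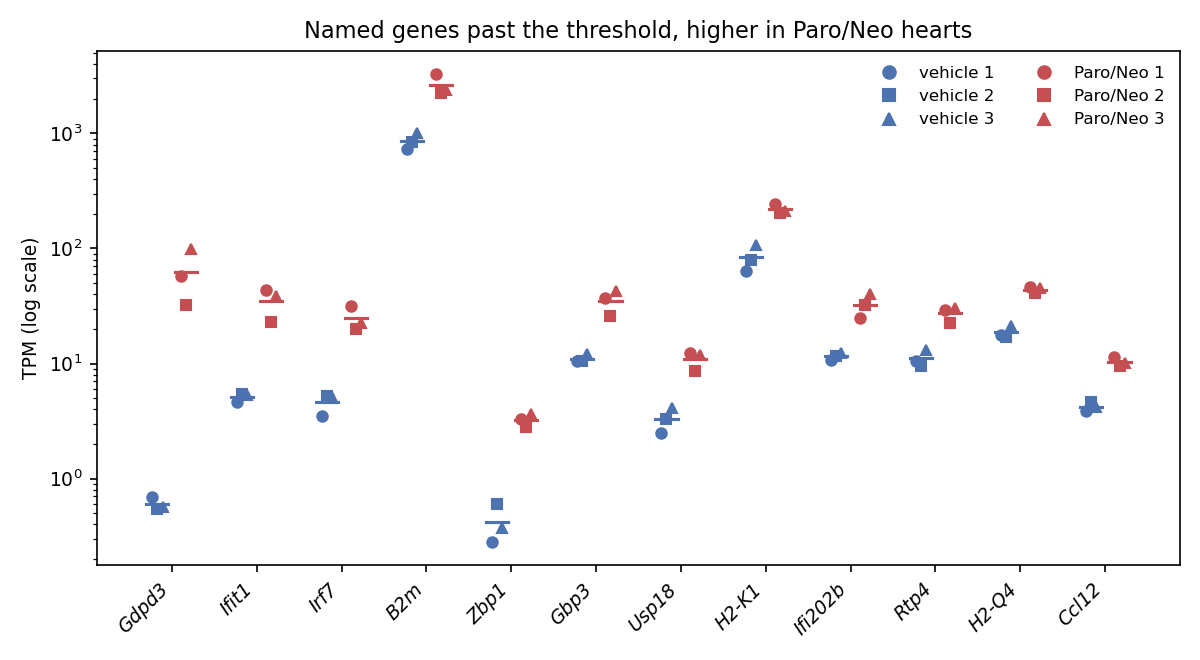
TPM per library on a log axis for the 12 genes of the naming rule that rose in Paro/Neo hearts, leaving out Snord69, which was listed at 0 in vehicle hearts. Points are mice, blue for vehicle and red for Paro/Neo, and horizontal lines are group means. Gdpd3 is at 0.546 to 0.686 TPM in vehicle and 32.3 to 98.0 TPM in Paro/Neo hearts, and the groups overlap for none of the 12 genes.

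In all, 15 of 12409 tested genes were higher and 2 lower in Paro/Neo hearts (limma on log2(TPM + 1), Benjamini-Hochberg adjusted p under 0.05). Without adjustment, 402 genes were higher and 542 lower at p under 0.05, and the groups did not overlap for 1769 genes, 14.26% of those tested, where chance gives 10%. The higher genes include 2 with clone names, Gm4841 and I830012O16Rik, the second annotated as Ifit3b. Snord69, a small nucleolar RNA, was also called, with 1 read in each treated and 0 in each vehicle library. On the lower side stood 2210407C18Rik, on chromosome 11 at 58608204 to 58616075, which fell from 14.4 TPM ± 4.44 to 3.35 TPM ± 0.87 (adjusted p 0.0402), and Mir5136, with 1 to 2 reads in vehicle and 0 in treated libraries. The calls of Snord69 and Mir5136 thus rest on 1 or 2 reads per library. Small p values among lower genes not past the threshold also belonged to AI593442, Mir24-2, Glipr2 (12.5 TPM ± 1.16 against 6.95 TPM ± 0.87), the retinoic acid synthesis gene Aldh1a2 (6.23 TPM ± 0.93 against 3.13 TPM ± 0.56), Tubb4a, Eln and Col5a2, with adjusted p from 0.0778 to 0.197. Mir24-2, too, had only 1 to 2 reads in vehicle and 0 in treated libraries. The count of higher genes depended on which library was left out. It was 4, 8 and 6 without vehicle replicate 1, 2 and 3, and 6, 23 and 6 without Paro/Neo replicate 1, 2 and 3, while lower genes numbered 0 to 4. In all 6 of these fits, 4 of the 17 called genes stayed past the threshold, namely Gdpd3, Ifit1, Irf7 and Snord69. The lower gene 2210407C18Rik stayed past it in 0 of the 6 fits. Those fits kept the 12409 genes; with the filter on low values applied anew, which drops Gdpd3 when a treated heart is left out because only the 3 treated hearts exceed 1 TPM, 0 genes passed without Paro/Neo replicate 1 (limma, 894 at an unadjusted p under 0.05), and 0 were higher without Paro/Neo replicate 3 (1121 unadjusted) and 1 without vehicle replicate 1.

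Genes of the interferon response moved together. All 37 tested members of the list were higher in Paro/Neo hearts, with a median log2 change of 1.15. Of these, 7 passed over all genes tested and 33 passed adjusted over the list alone. Beside the genes above, Isg15, a ubiquitin-like modifier, was at 6.18 TPM ± 1.02 in vehicle and 16.98 TPM ± 6.16 in treated hearts. Igtp, an immunity-related GTPase, spread from 15.045 TPM ± 3.93 to 120 TPM ± 116. Cxcl9, Irf1, Gbp2 and Gbp4 did not pass even over the list alone. Each treated heart stood above each vehicle heart, with list medians of 1.42, 0.85 and 1.35 above the vehicle mean in Paro/Neo replicates 1 to 3, against -0.14 to 0.16 in vehicle. Camera with the preset correlation gave the list an adjusted p of 2.53e-50. With an estimated correlation the adjusted p was 0.244, and by fry it was 0.0516 for one direction and 0.0136 for either. Without Paro/Neo replicate 1, 37 of 37 members were still higher, 3 past the threshold over all genes and 35 adjusted over the list alone. The count of members past the threshold over all genes was 2, 3 and 3 without vehicle replicate 1, 2 and 3, and 10 and 2 without Paro/Neo replicate 2 and 3.

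Macrophage and monocyte markers were higher by a smaller margin, a median log2 change of 0.18 over 26 genes, of which 20 were higher and 6 lower (camera adjusted p 0.000728, adjusted p 0.365 with an estimated correlation). Past the threshold over the list alone were the protease gene Ctss (37.8 TPM ± 1.29 to 55.3 TPM ± 4.69) and the Fc receptor gene Fcgr1 (2.13 TPM ± 0.70 to 4.51 TPM ± 0.96), and none passed over all genes. Over the list alone, 0 members passed by limma without vehicle replicate 1, 2 or 3 or Paro/Neo replicate 3, 1 without Paro/Neo replicate 2 and 3 without Paro/Neo replicate 1. The abundant macrophage transcript Lyz2 was at 359 TPM ± 54.7 and 371 TPM ± 60.8. In the neutrophil and mast cell list, S100a8 was at 4.23 TPM ± 1.26 against 10.1 TPM ± 1.00 and passed over the list alone, while the list did not. The chemokine gene Ccl5 was at 0.322 TPM ± 0.35 (0 to 3 reads per library) against 2.05 TPM ± 0.24 (7 to 8 reads) and passed over its list of cytokines alone. Only 3 lymphocyte markers were high enough to test, so that list was left untested.

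Genes of the extracellular matrix and of fibroblasts were lower in treated hearts. Of 38 tested members, 37 were lower and 1 higher, with a median log2 change of -0.62. None passed over all genes and 16 passed adjusted over the list alone, among them elastin, Eln (16.8 TPM ± 2.68 to 6.47 TPM ± 2.54), the fibrillar collagen genes Col5a2 (20.3 TPM ± 0.13 to 10.9 TPM ± 2.91) and Col3a1 (219 TPM ± 3.84 to 129 TPM ± 42.5), and the microfibril genes Fbn1 (32.9 TPM ± 5.42 to 17.2 TPM ± 4.74) and Mfap4 (37.6 TPM ± 2.27 to 14.7 TPM ± 6.91). Col1a1 did not pass, at 32.4 TPM ± 3.88 and 19.9 TPM ± 10.3. The fibroblast genes Dcn (1842 TPM ± 30.0 and 1820 TPM ± 85.1) and Pdgfra (29.5 TPM ± 1.11 and 27.6 TPM ± 5.54) differed by less than the spread between mice. Camera gave the list an adjusted p of 2.88e-17, and the adjusted p was 0.461 with an estimated correlation. The library that stood apart moved most: relative to the vehicle mean, the list median was -1.02 in Paro/Neo replicate 1, -0.29 in replicate 2 and -0.38 in replicate 3. With array weights the median was -0.39. Without Paro/Neo replicate 1 it was -0.36, with 33 of 38 members lower and 17 past the threshold over the list alone. Over the list alone, 8, 0 and 2 members passed without vehicle replicate 1, 2 and 3 (limma; 703 genes had an unadjusted p under 0.05 without vehicle replicate 2), and 25 passed without Paro/Neo replicate 2.

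**Figure D2:**
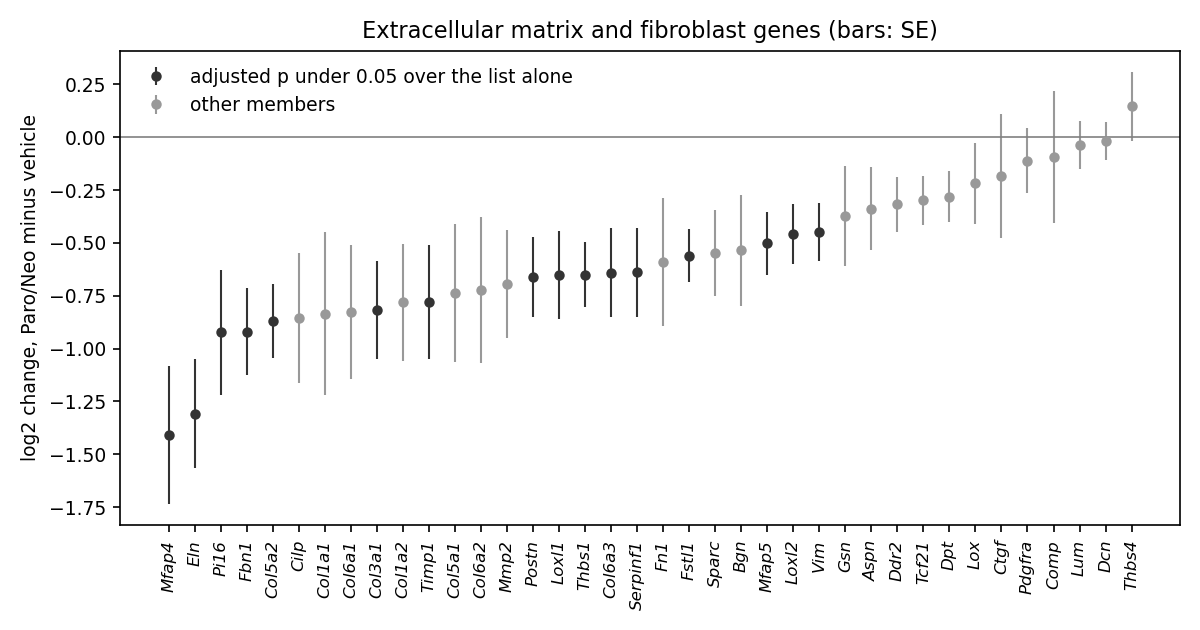
Log2 change between Paro/Neo and vehicle hearts, on the log2(TPM + 1) scale, for the 38 tested genes of the extracellular matrix and fibroblast list (points, with bars for the SE; n = 3 mice per group). Dark points are the 16 genes past an adjusted p of 0.05 over the list alone. Mfap4 and Eln lie lowest, at -1.41 and -1.31, and Thbs4 is the 1 member above 0.

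Lists of endothelial, smooth muscle and epicardial genes were also lower. Among 30 endothelial genes 23 were lower, with a median log2 change of -0.27 (camera adjusted p 0.000656, adjusted p 0.772 with an estimated correlation), and the apelin receptor gene Aplnr (32.1 TPM ± 7.47 against 18.3 TPM ± 0.84) and Icam2 (50.1 TPM ± 1.77 against 36.0 TPM ± 3.83) passed over the list alone. Without Paro/Neo replicate 1, 3 endothelial genes did so, without vehicle replicate 3 only 1, and by limma 0 without any 1 of the other 4 libraries. Of 19 smooth muscle and pericyte genes 15 were lower, with a median of -0.18 (camera adjusted p 0.0301, adjusted p 0.772 with an estimated correlation), led by Mcam (22.5 TPM ± 3.28 against 15.5 TPM ± 2.17) and Vtn. Both lists lost their call without Paro/Neo replicate 1, at adjusted p 0.0537 and 0.256 by camera, with medians of -0.10 and -0.07; the smooth muscle list also lost it without vehicle replicate 1 (0.0734) or 3 (0.146), with array weights (0.0646), with the GC correction (0.0648) and without a filter (0.0719), and its median was -0.29 without Paro/Neo replicate 3. Per library, Paro/Neo replicate 3 lay at 0.06 for smooth muscle and -0.005 for endothelial genes, above or within the range of the vehicle hearts. Of 7 epicardial and mesothelial genes 6 were lower, Aldh1a2 past the threshold over the list alone and Wt1 at 2.37 TPM ± 0.37 against 1.45 TPM ± 0.31, with a list median of -0.19 (camera adjusted p 0.00487, adjusted p 0.365 with an estimated correlation). That median was -0.36 without Paro/Neo replicate 2, -0.29 without vehicle replicate 3, -0.31 with a pseudocount of 0.1 and -0.30 with voom, and the endothelial median was -0.17 with array weights.

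**Figure D3:**
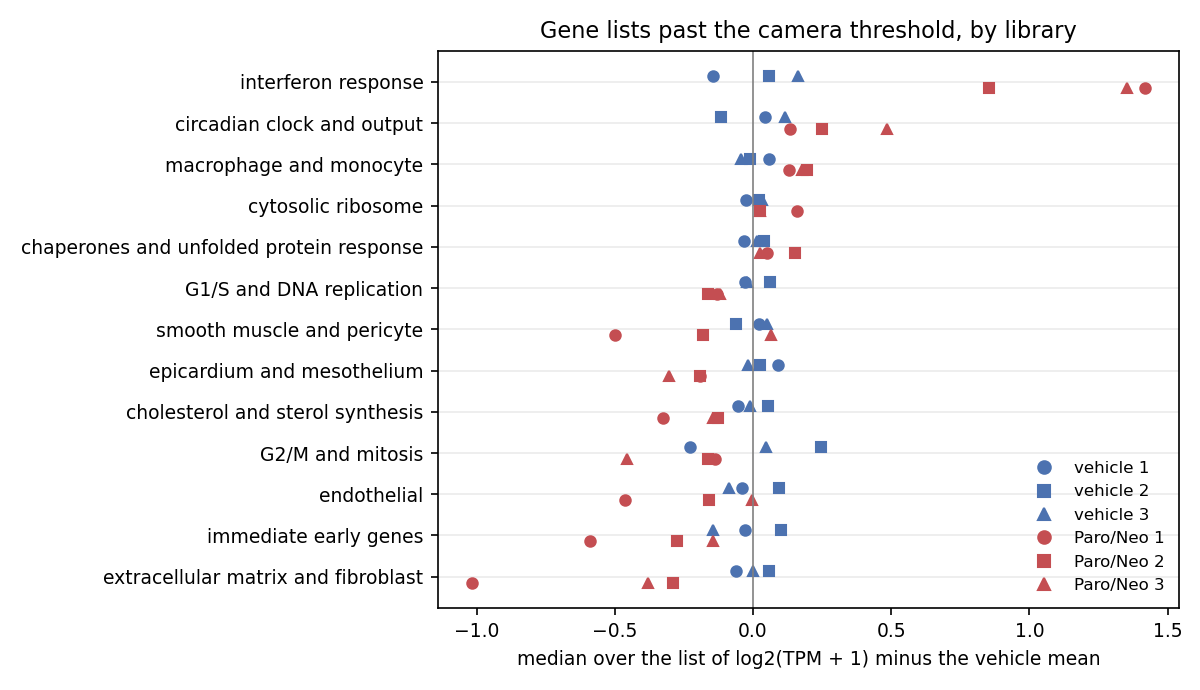
For each of the 13 gene lists past the camera threshold, the median over the list of each library's log2(TPM + 1) minus the vehicle mean (x axis), with blue symbols for vehicle and red symbols for Paro/Neo hearts, one per mouse. The interferon list lies at 0.85 to 1.42 in treated hearts, and the matrix and fibroblast list at -1.02 to -0.29 with Paro/Neo replicate 1 lowest.

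Lists of cell division genes were lower in treated hearts. Of 25 tested genes of G2/M and mitosis 22 were lower and 3 higher, with a median log2 change of -0.25 (camera adjusted p 0.000829, adjusted p 0.772 with an estimated correlation), and none passed, even over the list alone. The smallest p belonged to Incenp (2.34 TPM ± 0.23 against 1.43 TPM ± 0.16) and the kinetochore gene Nuf2 (1.46 TPM ± 0.22 against 0.753 TPM ± 0.16). Of 30 genes of G1/S and DNA replication 24 were lower, with a median of -0.11 (camera adjusted p 0.0223, adjusted p 0.444 with an estimated correlation), led by the cyclin genes Ccnd3 (25.8 TPM ± 2.84 against 19.0 TPM ± 2.87) and Ccnd1 (42.1 TPM ± 10.9 against 28.2 TPM ± 2.82), neither of them past the threshold. The G2/M call was lost without Paro/Neo replicate 3, at a median of -0.14 and an adjusted p of 0.157, and its median was -0.44 without vehicle replicate 1; under a stricter filter on low values the median was -0.02 and the adjusted p 0.96. The groups overlapped for G2/M, with vehicle replicate 1 at -0.23, below Paro/Neo replicates 1 and 2 at -0.14 and -0.16, and Paro/Neo replicate 3 at -0.45. The G1/S call was lost without vehicle replicate 2 (adjusted p 0.0966) or Paro/Neo replicate 2 (0.0984) or 3 (0.073), and its median was -0.18 with a pseudocount of 0.1.

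Adult cardiomyocyte genes did not pass as a list over all 6 libraries. Of 33 adult cardiomyocyte genes 17 were higher and 16 lower, with a median log2 change of 0.005 (camera adjusted p 0.552, adjusted p 0.841 with an estimated correlation). Without Paro/Neo replicate 1, 20 were higher, with a median of 0.05 (camera adjusted p 0.0179, adjusted p 0.522 with an estimated correlation), and 2 passed over the list alone, against 1 without vehicle replicate 1 and 0 by limma without any 1 of the other 4 libraries. Tcap, which encodes the titin cap of the sarcomere, was at 1691 TPM ± 277 against 2683 TPM ± 93.2 and passed over the list alone, and the mitochondrial creatine kinase gene Ckmt2 was at 5039 TPM ± 456 against 3896 TPM ± 341 and did not. Neither fetal and stress-induced cardiac genes (7 of 18 higher, adjusted p 0.962) nor genes of calcium handling (17 of 31 higher, adjusted p 0.706) nor nuclear genes of oxidative phosphorylation (20 of 49 higher, adjusted p 0.924) passed. Transcripts encoded in the mitochondrion were not analysed here.

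Genes of the circadian clock and its output were higher as a list, and immediate early genes, which respond to stimuli within minutes, were lower. The circadian list had 16 of 23 members higher, with a median log2 change of 0.27 (camera adjusted p 0.00208, adjusted p 0.461 with an estimated correlation), and 4 members passed over the list alone. That count was 14 without Paro/Neo replicate 1 (11 higher, 3 lower) and 10 without vehicle replicate 3 (8 higher, 2 lower), and by limma 0 without any 1 of the other 4 libraries. Tef (33.4 TPM ± 5.58 to 49.8 TPM ± 1.46), Nr1d2 (99.5 TPM ± 15.2 to 141 TPM ± 9.42) and Hlf (7.82 TPM ± 1.66 to 13.8 TPM ± 3.20) were higher, and Npas2, a partner of Arntl in the core activator, was lower (1.97 TPM ± 0.69 to 0.639 TPM ± 0.25). Arntl was at 13.3 TPM ± 4.26 against 8.09 TPM ± 0.98 and did not pass. The list median was 0.43 without Paro/Neo replicate 1 and 0.13 without Paro/Neo replicate 3. Of 21 immediate early genes 17 were lower, with a median of -0.36 (camera adjusted p 0.000199, adjusted p 0.748 with an estimated correlation), and Fosl2, Btg2 and Jun passed over the list alone. Jun was at 26.0 TPM ± 4.62 against 17.3 TPM ± 2.10, and the list median was -0.23 without Paro/Neo replicate 1. Relative to the vehicle mean, the list median was -0.5895, -0.275 and -0.1437 in Paro/Neo replicates 1 to 3. Vehicle replicate 3, at -0.1436, was level with Paro/Neo replicate 3. Over the list alone 0 immediate early genes passed by limma without Paro/Neo replicate 1 or 2 or vehicle replicate 1 or 2, and 7 without Paro/Neo replicate 3.

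Sterol synthesis genes were lower in 21 of 26 members, with a median of -0.20 (camera adjusted p 0.00208, adjusted p 0.444 with an estimated correlation) and Cyp51 (22.7 TPM ± 2.67 against 16.3 TPM ± 1.83) and Pmvk at the smallest p. Paro/Neo replicate 1 moved most, with a sterol list median of -0.33 relative to the vehicle mean, against -0.13 and -0.14 in replicates 2 and 3. Without it the median change was -0.14. Of 44 cytosolic ribosome genes 33 were higher, with a median of 0.09 (camera adjusted p 0.00487, adjusted p 0.772 with an estimated correlation), and of 31 chaperone and unfolded protein response genes 19 were higher, with a median of 0.06 (camera adjusted p 0.0416, adjusted p 0.772 with an estimated correlation) and Dnajb9 (66.7 TPM ± 4.22 against 99.1 TPM ± 20.6) at the smallest p. No member of these 3 lists passed over the list alone. The ribosome call was lost without Paro/Neo replicate 1 (adjusted p 0.214) or vehicle replicate 1 (0.0734), with medians of 0.03 and 0.05, and with array weights (0.0646, median 0.05), and its median was 0.14 without Paro/Neo replicate 3 and 0.15 with the GC correction. The chaperone call was lost without vehicle replicate 1 (0.186) or 3 (0.0659) or Paro/Neo replicate 2 (0.67), with medians of 0.03, 0.04 and 0.01, and its median was 0.04 without vehicle replicate 2 and with the GC correction. It was also lost without a filter (0.0733), with the stricter filter (0.123), with quantile normalization (0.107, median 0.04) and without an intensity trend (0.0521), in all under 11 of 22 alternatives. Per library, the groups overlapped for both lists. The ribosomal RNA feature Rn45s was lower in treated hearts, at 8123 TPM ± 779 in vehicle and 3574 TPM ± 2575 in treated hearts (limma adjusted p 0.522). Its groups did not overlap, at 7622 to 9020 TPM in vehicle and 1155 to 6280 TPM in treated hearts. Whether this came from library preparation or from the treatment was not tested.

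In total 13 of 37 lists passed with the preset correlation, 5 higher and 8 lower, and 0 passed by camera with an estimated correlation or by fry for one direction, adjusted over the lists, against 3 and 6 at an unadjusted p under 0.05. By fry for either direction 5 lists passed, those of the interferon response (0.0136), macrophages and monocytes (0.0136), cytokines (0.0136), the epicardium (0.0169) and cell cycle inhibitors (0.042). The other 24 lists had camera adjusted p from 0.0948 to 0.962. Without Paro/Neo replicate 1, the lists of fatty acid oxidation (camera adjusted p 0.0214), erythrocytes (0.0404), cytokines (0.036), the glucocorticoid response (0.0289) and adipocytes (0.036) also passed, with adjusted p from 0.388 to 0.721 with an estimated correlation. Without vehicle replicate 1 the lists of fatty acid oxidation (0.00319), erythrocytes (0.000244), the glucocorticoid response (0.00634) and the atrium, conduction and valve (0.0122) did, with adjusted p from 0.412 to 0.741 with an estimated correlation. Without Paro/Neo replicate 2 those of glycolysis (0.0453) and of YAP, ErbB and growth factor signalling (0.0408) passed, and without Paro/Neo replicate 3 the latter (0.0334) and that of Schwann cells and neurons (0.0459), with adjusted p from 0.637 to 0.862 with an estimated correlation. Among them, Igf1 (15.02 TPM ± 0.54 against 10.3 TPM ± 0.37) passed over the list of YAP, ErbB and growth factor signalling alone, a count of 1 that was 0 by limma in each fit leaving out 1 library but that without Paro/Neo replicate 3. In the lists of cytokines, cell cycle inhibitors, neutrophils and mast cells, adipocytes, and fetal cardiac genes the median lay below 0 while camera's direction was up.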

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

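Tests chosen after the data were seen are voom on the inferred reads, the GC correction, that correction with the block, leaving out short and ribosomal RNA features, and keeping the same 12409 genes in the fits that leave out a library. Against 15 genes higher and 2 lower, no filter gave 5 and 1, no intensity trend 8 and 1, the replicate block with the GC correction 4 and 1, array weights 22 and 4, voom 25 and 3, and an adjusted p threshold of 0.10 gave 34 and 4. Lower genes numbered 1 with the stricter filter, with quantile normalization and without short and ribosomal RNA features. Leaving out 1 library gave 4 to 23 higher and 0 to 4 lower genes. With the filter applied anew to the remaining 5 libraries, 0 to 19 were higher and 0 to 4 lower, with 0 in either direction by limma without Paro/Neo replicate 1 (894 at an unadjusted p under 0.05). The number of lists past the threshold, 13, was 11 to 16 under the other settings, except for 0 by camera with an estimated correlation and 0 by fry for one direction (3 and 6 unadjusted). By fry for either direction 5 passed. Without a filter more genes were tested, and with a library left out the fit had fewer samples. For the other settings the cause was not tested.

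The title numbers, on which the replicate block rests, gave no sign of pairing: deviations from the group means correlated at -0.053, -0.036 and -0.122 for numbers 1, 2 and 3. By the descriptions' numbers, which share only 2 and 3, they correlated at -0.052 and 0.011. With the replicate block 25 genes were higher and 2 lower, 15 of those 27 shared with the 17, and the chaperone list had an adjusted p of 0.0858.

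Reversals of sign were in genes that were not called, with log2 changes near 0. Cdkn1b was at 0.0112 with median-of-ratios scaling, 0.0317 with array weights and 0.0102 with voom, and Dcn at 0.0054, 0.0077 and 0.0053. With array weights Cdkn1a was at 0.0202, Pdgfra at 0.0354 and Lyz2 at -0.0499. Meis1 was at -0.0314 with the GC correction and with the replicate block and GC correction, and at -0.0048 without short and ribosomal RNA features. With 1 library left out, Meis1 ranged from -0.0631 to 0.0601, Cdkn1a from -0.3034 to 0.2192, Cdkn2b from -0.2221 to 0.0131, Cdkn1b from -0.1303 to 0.1199, Pdgfra from -0.2154 to 0.0594, Dcn from -0.0459 to 0.02, Lyz2 from -0.0833 to 0.1309 and Ppp4c from -0.0573 to 0.1316. The cause was not tested.

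Of the 13 lists past the threshold, 0 changed the sign of their median under any setting, while 15 of the other 24 did with 1 library left out. The 13 were picked for their shift in these same data, and the fits share libraries, so this contrast was largely fixed in advance. Over all settings the interferon median was 1.00 to 1.26 and the matrix median -0.73 to -0.36. Splitting the 6 libraries 3 against 3 gives 10 splits, too few for a share under 0.05. The real split gave 15 higher genes (1 of 10 splits gave as many in its larger direction, highest other 7), 2 lower genes (3 of 10, highest other 7) and 13 lists (2 of 10, highest other 13). Leaving out mitochondrial genes moved nothing, with 0 in the table, and negative binomial models were not run. A depth of 9556387 reads or more leaves genes of a few reads, such as Cdkn2a, untested.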

Other observations

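Tests chosen after the result was seen are those of macrophage markers, of chromosome 17, of the matrix list without Paro/Neo replicate 1, of on and off genes and of the neighbours of Gdpd3.

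None of 3 genes of MHC class II presentation, chosen after their values were seen and in no tested list, passed the threshold over all genes. H2-Aa was at 73.1 TPM ± 9.22 in vehicle and 201 TPM ± 69.6 in Paro/Neo hearts (SD, n = 3 each; limma adjusted p 0.0943), H2-Ab1 at 24.5 TPM ± 2.71 and 58.4 TPM ± 32.6 (adjusted p 0.441), and Cd74, the invariant chain, at 52.9 TPM ± 7.25 and 133 TPM ± 55.8 (adjusted p 0.208). Of the interferon-inducible GTPases, Irgm1 was at 27.2 TPM ± 3.36 and 94.0 TPM ± 38.2 (adjusted p 0.0901) and Iigp1 at 67.8 TPM ± 21.3 and 310.1 TPM ± 283 (adjusted p 0.481). On chromosome 18, Gm4841 (60268305 to 60273272), F830016B08Rik (60293380 to 60303016) and Iigp1 (60376027 to 60392634) lie within one stretch. Gm4841 was at 0.609 TPM ± 0.34 and 56.4 TPM ± 51.4 (adjusted p 0.0426) and F830016B08Rik at 8.75 TPM ± 3.61 and 181 TPM ± 113 (adjusted p 0.0631). In Igtp, Iigp1, F830016B08Rik and Gm4841, Paro/Neo replicate 3 was the highest and replicate 2 the lowest of the treated hearts. These genes resemble each other in sequence, so their single values are uncertain.

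The interferon list was higher in treated hearts, and 3 other explanations were tested, of which the GC trend is technical. More macrophages and monocytes would raise their markers as a set, but those outside the interferon list had a median log2 change of 0.1787 (0.1197 to 0.2552 with 1 library left out). Of these, Lyz2 was at 0.05 and C1qa at 0.20. Ptprc, a gene of leukocytes in general and not among these markers, was also higher and by more, at 0.70 (limma adjusted p 0.236). More leukocytes of other kinds were not tested, as only 3 lymphocyte markers were high enough to test. Linked variants in the H2 region would act on chromosome 17, yet the 32 of 37 members elsewhere had a median of 1.193 (1.041 to 1.2856). These medians argue against either as the whole cause. After the GC correction the list's median was 1.1571 (1.0229 to 1.2902). The correction could hardly move it, as the list's median GC content was 49.51%, against 49.52% over all tested genes. A median of 1.0894 without Paro/Neo replicate 1 argues against the GC trend of that library as the whole cause. An effect of the treatment stays open as a hypothesis, as does an infection or another exposure shared within a group, for which no value was at hand.

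The matrix and fibroblast list was lower in treated hearts. The GC trend of Paro/Neo replicate 1 is argued against as the whole source by a median log2 change of -0.561 after the correction (-0.6875 to -0.3611 with 1 library left out), and that library alone by a median of -0.3644 without it. Fewer fibroblasts may also lower the list, and would lower identity markers as far as matrix genes. The 11 identity markers had a median of -0.3167 and the 18 matrix genes -0.7309, a difference of 0.4141, but it ranged from 0.1659 to 0.6129 with 1 library left out, so the test did not decide. A smaller share of fibroblasts, lower matrix expression and an effect of the treatment stay open.

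Gdpd3, on chromosome 7 at 126766334 to 126775649, was near off in the vehicle and on in the treated hearts. Reads running on from a neighbour that itself rose are argued against for the 5 genes within 50000 bases that had a position here. The largest rise among these 5 was 0.8657 TPM, in Ppp4c, against 62.1 TPM for Gdpd3. Features not matched to 1 annotated gene had no position, so a neighbour among them was not covered. With 1 library left out, the largest rise among the 5 was 0.5648 to 2.5966 TPM, against 44.4 to 77.2 TPM for Gdpd3. That test replaced an earlier one, which asked for log2 changes of neighbours under 0.5 and did not decide. In the earlier one Fam57b, near 1 TPM, was at 0.48, and the highest neighbour at 0.54 with 1 library left out. Reads running on from a neighbour that did not rise were not tested. Of the neighbours, Mapk3 (45.8 TPM in vehicle and 41.6 TPM in treated hearts) and Ypel3 (40.6 and 34.9 TPM) were expressed in both groups. CD1 mice are outbred, so a variant in these mice may also turn a gene on or off, but the cause of such gaps was not tested. Of 10 genes with a gap of 8-fold or more between sets of libraries among 11910 searched, 8 cut across the groups. The other 2 followed them, Gdpd3 and Gm4841. Only the 5 that part 3 libraries from 3 can follow the groups, and 2 did. The search was chosen after the gap in Gdpd3 was seen, and Gm4841 was already among the called genes. That share can therefore not be set against chance. Of the other 3, Rpl26 and a pseudogene share their reads, which leaves Rpl26 and Iqcg. Iqcg ends at 33056218 on chromosome 16, and Rpl35a, another of the 10, starts at 33056453, so their gaps may not be separate. As Rpl26, Rpl35a and Rps2 among the 10 are ribosomal protein genes, the gaps do not show that variants turn genes off. A variant that fell by chance with the groups and an effect of the treatment cannot be told apart for Gdpd3, as no genotypes were used here.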
